A study of Homo sapiens with 6 samples.

How the data were processed

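RNA was measured in 6 libraries of THP-1 cells, an established human acute monocytic leukaemia line. Per the labels, 3 libraries came from cells given 1 µM of a compound named only by the code 1a for 16 h, and 3 came from untreated cells. No vehicle is named for the untreated cells. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a directional NEBNext Ultra kit, and single reads of 75 bp were sequenced on an Illumina NextSeq.

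The deposited values are whole-number read counts per gene, in 1 table per library and not pooled. Per the submitters' processing notes, which give names without roles, the tools were bcl2fastq, Trimmomatic 038, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 1.22.2, and the builds were hg38 and GRCh38. The strand setting of the counting and the annotation release are not given in the sources used here. Reads of a gene and its antisense partner therefore may not be separable, and genes with near-identical copies are uncertain. The authors also deposited a list of 20 genes as higher and a list of 20 genes as lower with 1a, with log2 fold changes. The rule that selected them is not given in the sources used here.

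Each count table held 58395 genes and 5 summary rows that name no gene, which were left out of library sizes and tests. Reads outside annotated features made up 8.61% to 10.1% of all reads tabulated, and reads aligned to more than 1 place made up 7.39% to 8.09%. GENCODE release 29 on GRCh38 was used for coordinates and gene types, and 58275 identifiers matched it. Coordinates are 1-based gene spans. Transcript GC content and length were those of the longest annotated transcript of each gene, known for 99.9% of the genes tested.

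Counts were tested with edgeR's quasi-likelihood test in R, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), the group as the only term, and Benjamini-Hochberg adjustment over 16151 genes. The test was two-sided and a gene was called at an adjusted p under 0.05. The standard error printed with a log2 fold change is the one implied by the test statistic. Levels are CPM (counts scaled to library size) with TMM factors, as mean ± SD over 3 libraries. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.22, and all 6 were kept.

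The design, the genes to name and 50 gene lists were fixed before the data were examined. The named genes were the 12 largest and 12 smallest log2 fold changes among called genes with an HGNC-type symbol, a mean log2 CPM of at least 1 and no overlap between groups, the 5 smallest adjusted p-values in each direction, up to 4 members with the smallest adjusted p of each list described, and the 5 genes of each deposited list with the largest change. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over 43 lists. Camera with an estimated correlation and fry were alternatives. Fry tests a list against no change and not against the other genes. Of 839 list entries, 837 were matched to a gene. Other alternatives were RLE, upper-quartile and total-count scaling, no count filter or CPM over 1 in at least 3 libraries, DESeq2, limma-voom, the replicate number as a block, protein-coding genes only, an adjusted p under 0.01, and leaving out each library. Removal of a smooth trend on transcript GC and length, camera with an estimated correlation after that removal, a test against a 1.2-fold change, and the share of reads outside features as a covariate were chosen after seeing the data.

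The procedure was tested on simulated counts with 200 changed genes. In the simulated comparison of 1a with untreated over 15913 genes, edgeR recovered 26 of 50 genes changed 1.2-fold, 44 of 50 changed 1.5-fold, and 50 of 50 at both 2-fold and 4-fold, with 10 false calls among 180. With no gene changed, 3 of 15940 simulated genes were called. With a length trend added to the simulated 1a libraries, 497 of 665 calls over 15964 genes were false, and 9 of 171 were false after removal of the trend, with 99 of 100 genes changed at least 2-fold recovered. This added trend used the same transcript lengths as the removal, alike in all simulated 1a libraries and without a GC term. It therefore does not show how well the removal works on the real libraries.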

Results

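Gene counts were compared between 3 libraries of THP-1 cells treated with 1 µM 1a for 16 h and 3 libraries of untreated THP-1 cells. The design asks which transcripts differ when the compound is present. Libraries held between 23700110 and 25710513 gene counts, and 24325 to 25104 genes had at least 1 count. Mitochondrial genes took 4.91% ± 0.0276 of gene counts with 1a and 4.95% ± 0.163 without (SD, n = 3). The correlation of log2 CPM across genes was 0.994 to 0.995 within groups and 0.987 to 0.993 between groups. The first principal component held 49.0% of the variance and separated the groups. It also ranked the libraries in the order of their slopes of log2 expression on transcript length, a trend described below.

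Genes of the antioxidant programme driven by the transcription factor NRF2 rose in cells treated with 1a. Of 22 tested members of the fixed list, 17 were higher, 1 was lower and 4 were not called, both over all genes and adjusted over the list alone (camera adjusted p = 4.76e-58, median log2 fold change 0.72). With an estimated correlation the list had an adjusted p = 0.0998. NQO1, a quinone reductase (ENSG00000181019, chromosome 16, 69706996 to 69726951), rose from 42.5 ± 5.66 to 149 ± 7.71 CPM (SD, n = 3), a log2 fold change of 1.81 (standard error 0.0783, edgeR adjusted p = 3.23e-08). HMOX1, which degrades heme (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 0.772 ± 0.103 to 3.50 ± 0.959 CPM, a log2 fold change of 2.18 (standard error 0.231, edgeR adjusted p = 3.14e-05). PGD and ME1, both sources of NADPH, rose by log2 fold changes of 1.17 and 1.40. OSGIN1 and PIR rose by 1.81 and 1.82 on that scale. SLC7A11, a cystine transporter named after its value was seen as the member that was lower, fell by 0.34 on the log2 scale (edgeR adjusted p = 0.00371), a call that ended after removal of a trend on transcript length and GC content (-0.07, adjusted p = 0.412). The members not called were GCLC, SRXN1, AKR1C1 and ABCC2, also named after their values were seen.

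The ferritin subunits, which store iron and are also in this list, rose. FTL (ENSG00000087086, chromosome 19, 48965301 to 48966878) rose from 1854 ± 140 to 4350 ± 378 CPM (SD, n = 3), a log2 fold change of 1.23 (standard error 0.0649, edgeR adjusted p = 1.91e-07). FTH1 (ENSG00000167996, chromosome 11, 61959718 to 61967660) rose from 89.3 ± 2.45 to 280 ± 37.3 CPM, a log2 fold change of 1.65. The ferritin pseudogene FTLP3 rose from 66.4 ± 4.24 to 147 ± 8.04 CPM. These genes share sequence with several copies, so their separate levels are uncertain.

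**Figure D1:**
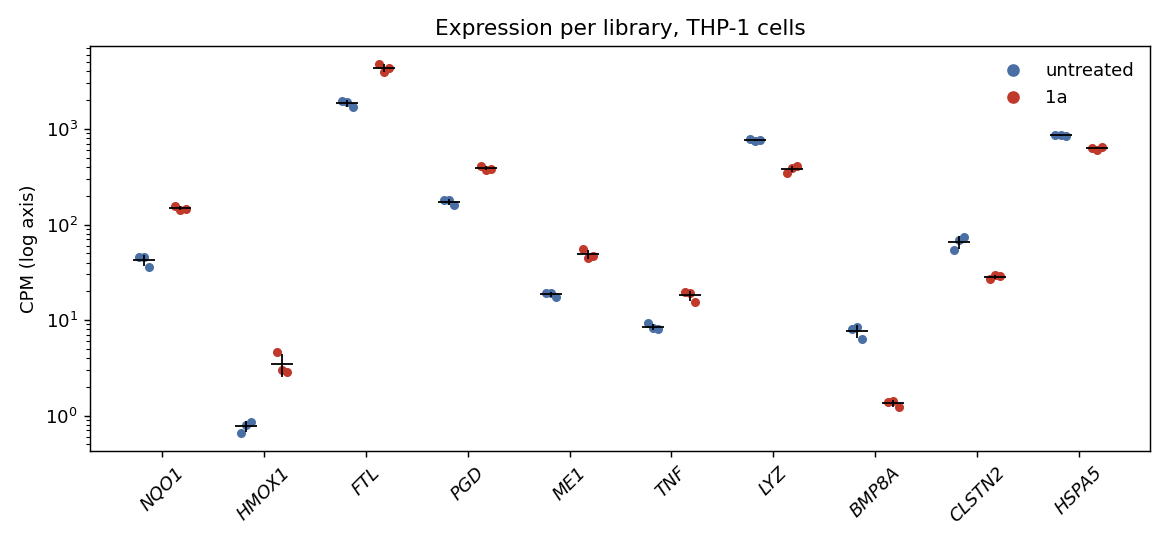
CPM of 10 named genes in each library, on a log axis, with untreated libraries in blue and 1a libraries in red; bars give the mean and the SD of 3 libraries. The 3 treated libraries lay above all untreated libraries for NQO1, HMOX1, FTL, PGD, ME1 and TNF, and below them for LYZ, BMP8A, CLSTN2 and HSPA5.

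Other genes with large increases were MSC, a transcriptional repressor, with a log2 fold change of 2.15 (standard error 0.162), PANX2, a channel protein, with 1.72, HGD, an enzyme of tyrosine breakdown, with 1.69, and TBXAS1, thromboxane synthase, with 1.63. TRIM16L rose by a log2 fold change of 1.99 and is uncertain because of its paralog TRIM16. ANXA2, a membrane-binding protein, rose from 178 ± 1.96 to 306 ± 9.72 CPM (SD, n = 3). The low-count gene NMRAL2P rose by 4.08 on the log2 scale. TREML3P had 43 counts over the 1a libraries and 0 over the untreated ones, which is at least 14.6-fold higher against a floor of 3 counts over the group. NPIPA8, of a multicopy family, had 84, 225 and 29 counts with 1a and 2, 3 and 2 without (edgeR adjusted p = 0.0483). That call was lost without untreated replicate 1 (adjusted p = 0.144), untreated replicate 2 (0.149), untreated replicate 3 (0.165) or 1a replicate 1 (0.117), and 1a replicate 2 held most of its counts.

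Among the genes that fell, BMP8A, a bone morphogenetic protein (ENSG00000183682, chromosome 1, 39491646 to 39525935), went from 7.64 ± 1.15 to 1.35 ± 0.105 CPM (SD, n = 3), a log2 fold change of -2.49 (standard error 0.156, edgeR adjusted p = 2.79e-07). It has a close paralog, BMP8B. LYZ, the lysozyme gene of myeloid cells (ENSG00000090382, chromosome 12, 69348341 to 69354234), fell from 768 ± 14.0 to 381 ± 28.7 CPM, a log2 fold change of -1.01 (standard error 0.0497, edgeR adjusted p = 3.23e-08). MS4A3, a gene of myeloid progenitors, fell by 0.97 on the log2 scale, SESN3 by 0.91, and MCM7, a subunit of the replicative helicase, by 0.73. CLSTN2, REL, ENTPD7 and UGT3A2 had log2 fold changes of -1.22, -1.11, -1.02 and -0.98. SAMD11, KCND2, ROS1, GJD3, NBEAL1 and LINC02257 fell by between 1.11 and 1.30 on the log2 scale, each from under 6 CPM. GOLGA8M, of a multicopy family, and ZNF66 had -1.28 and -1.14. The GOLGA8M call was lost without 1a replicate 1 (adjusted p = 0.0882), 1a replicate 3 (0.0633) or untreated replicate 3 (0.0629), and the ZNF66 call without 1a replicate 2 (0.0543) or 1a replicate 3 (0.0556).

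Genes of the unfolded protein response, which handle protein folding in the endoplasmic reticulum, fell. Of 18 tested members, 14 were lower and 1 was higher, and 15 were lower and 1 higher adjusted over the list alone (camera adjusted p = 1.23e-12, median log2 fold change -0.35, adjusted p = 0.171 with an estimated correlation). The chaperone HSPA5 fell from 860 ± 12.7 to 630 ± 18.5 CPM (SD, n = 3), a log2 fold change of -0.45 (standard error 0.0382). HYOU1, PDIA4 and HSP90B1 had log2 fold changes of -0.45, -0.41 and -0.36. SEC61B, named after its value was seen, was the member that rose (0.29). Aminoacyl-tRNA synthetase genes had 8 members lower and 2 higher of 16, the same adjusted over the list alone (camera adjusted p = 0.0379, median -0.07, adjusted p = 0.312 with an estimated correlation). WARS, IARS and EPRS fell by 0.43, 0.31 and 0.29 on the log2 scale and SARS rose by 0.19. This list was not called with upper-quartile scaling (adjusted p = 0.0995), or without 1a replicate 2 (0.0783) or untreated replicate 2 (0.0542).

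NF-kB and inflammatory cytokine genes rose in 10 of 18 tested members and fell in 0, the same adjusted over the list alone (camera adjusted p = 9.90e-06, median log2 fold change 0.41, adjusted p = 0.212 with an estimated correlation). TNF rose from 8.51 ± 0.636 to 18.1 ± 2.14 CPM (SD, n = 3), a log2 fold change of 1.09 (standard error 0.0962). BCL3, RELB and TNFAIP2 had log2 fold changes of 0.82, 0.66 and 0.39. REL, an NF-kB subunit, fell. Genes of MAPK output and immediate early response had 8 members higher and 1 lower of 20, the same adjusted over the list alone (camera adjusted p = 0.0375, median 0.11, adjusted p = 0.312 with an estimated correlation). DUSP4, FOS and ETV4 rose by 0.93, 0.49 and 0.29, and SPRED2 fell by 0.33 on the log2 scale. The MAPK call was lost without 1a replicate 2 (adjusted p = 0.0928) or untreated replicate 1 (0.0769).

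Genes of lysosomes and autophagy had 14 members higher and 5 lower of 29, and 16 higher and 5 lower adjusted over the list alone (camera adjusted p = 2.80e-05, median log2 fold change 0.19, adjusted p = 0.312 with an estimated correlation). SQSTM1, an autophagy receptor, rose by 0.68 on the log2 scale, the proteases CTSD and CTSB by 0.73 and 0.44, and the transcription factor TFEB by 0.43. Proteasome subunits had 18 members higher and 0 lower of 22, and 19 higher adjusted over the list alone (camera adjusted p = 4.60e-07, median 0.20, adjusted p = 0.543 with an estimated correlation). PSMB6, PSMB3, PSMB1 and PSMB4 rose by 0.37, 0.33, 0.29 and 0.27. Cytoplasmic ribosomal protein genes had 27 members higher and 0 lower of 30, and 29 higher adjusted over the list alone (camera adjusted p = 4.24e-09, median 0.19, adjusted p = 0.629 with an estimated correlation). After removal of a trend on transcript length and GC content, 16 of them were higher. RPS19, RPL18, RPS14 and RPL10A rose by 0.28, 0.27, 0.24 and 0.24. Glycolysis genes had 9 members higher and 1 lower of 20, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00338, median 0.14, adjusted p = 0.317 with an estimated correlation). PKM, GAPDH, ENO1 and SLC16A3 rose by 0.43, 0.29, 0.27 and 0.25.

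Stem, progenitor and KMT2A-fusion target genes had 8 members lower and 1 higher of 16, the same adjusted over the list alone (camera adjusted p = 0.0375, median log2 fold change -0.15, adjusted p = 0.543 with an estimated correlation). RUNX2, JMJD1C, FLT3 and CDK6 had log2 fold changes of -0.58, -0.36, -0.34 and -0.30, and HOXA9, named after its value was seen, rose by 0.19. This call was lost without 1a replicate 1 (adjusted p = 0.0540) or untreated replicate 2 (0.0542). Aryl hydrocarbon receptor target genes were called higher with 5 tested members, of which 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 3.81e-05, median 0.18, adjusted p = 0.171 with an estimated correlation). The members that rose were NQO1, which is also in the NRF2 list, and CYP1B1, a cytochrome P450 (0.67). TIPARP fell by 0.23 on the log2 scale (edgeR adjusted p = 0.0430), a call lost without 1a replicate 1 (0.193), 1a replicate 3 (0.0918), untreated replicate 2 (0.0811) or untreated replicate 3 (0.187). AHR itself had 0.18 (edgeR adjusted p = 0.207).

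Several calls ended under other settings. The stem and progenitor list was not called with limma-voom (adjusted p = 0.0817), CPM over 1 (0.0907) or protein-coding genes only (0.0803), nor were the aminoacyl-tRNA synthetase list (0.0683, 0.0755 and 0.0803) and the MAPK list (0.0817, 0.0512 and 0.0503). With a preset correlation of 0.05 these 3 lists had an adjusted p = 0.145. The aryl hydrocarbon receptor list was not called with limma-voom (0.0817). The ribosomal protein list was not called with fry (0.0710), which tests against no change and not against the other genes. NPIPA8 was not called with limma-voom (0.157) or without a count filter (0.103), and TIPARP was not called with DESeq2 (0.0722), upper-quartile scaling (0.0679) or total counts (0.0503). With the share of reads outside features as a covariate, the stem and progenitor list (0.1204), NPIPA8 (0.223), TIPARP (0.394), ROS1 (0.0530), ZNF66 (0.129), CDK6 (0.0768), FLT3 (0.0904), SARS (0.0728), SPRED2 (0.0608), ETV4 (0.0768) and GJD3 (0.0755) were not called. Of the 75 genes followed through the other settings, those whose calls ended in the test against a 1.2-fold change were NPIPA8, GOLGA8M, ZNF66, JMJD1C, CDK6, FLT3, TNFAIP2, TIPARP, IARS, EPRS, SARS, HSP90B1, ENO1, SLC16A3, GAPDH, RPL10A, RPS19, RPL18, RPS14, PSMB6, PSMB3, PSMB4, PSMB1, TFEB, SPRED2 and ETV4.

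**Figure D2:**
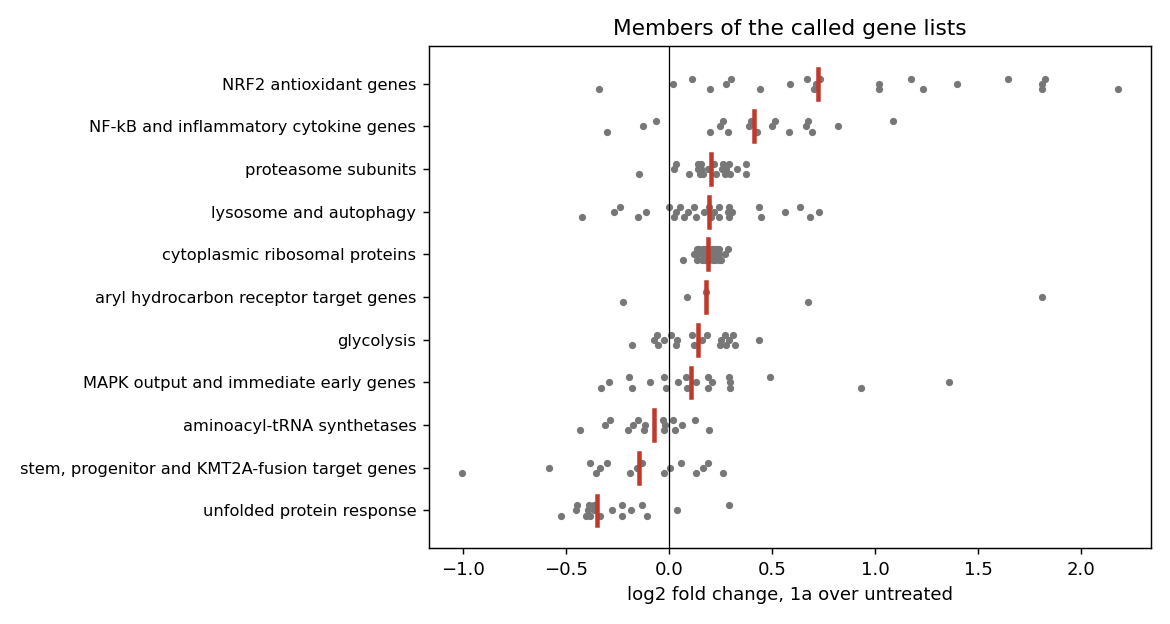
Log2 fold change of 1a over untreated for each tested member (grey points) of the 11 called lists, with the list's median as a red line. The NRF2 list had the highest median, 0.72, and the unfolded protein response list the lowest, -0.35.

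The other 32 tested lists were not called. Monocyte and macrophage markers had 8 members higher and 2 lower of 18 (camera adjusted p = 0.529). Granulocyte markers had 1 higher and 3 lower of 11 (adjusted p = 0.165), and DNA replication genes 4 higher and 7 lower of 23 (adjusted p = 0.0972). Both of these lists were called lower once a trend on transcript length and GC content was removed (adjusted p = 1.95e-05 and 0.000375), but not with an estimated correlation (0.457 and 0.507 after removal, 0.753 and 0.629 before). Lists with under 5 tested members had no list test. Among markers of other cell types, 2 of 4 tested lymphoid genes were higher, and none of the 3 tested megakaryocyte, epithelial and fibroblast genes was called over all genes. The single tested megakaryocyte and fibroblast genes were higher adjusted over their own lists (log2 fold changes 0.64 and 0.65). No erythroid marker passed the count filter. Among noncoding RNAs listed as signs of RNA quality, 1 of 4 tested was higher, and 3 were higher adjusted over the list alone, with a median log2 fold change of 0.51 and a lowest value of 0.16.

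Over the 16151 genes tested, 2481 were higher and 2822 lower with 1a. Of these 5303 genes, 89.0% changed by under 1.5-fold, and the median size was 1.21-fold. At least a 2-fold change was found for 111 genes higher and 59 lower. The groups did not overlap for 45.6% of the tested genes. Chance gives 10% for each gene, but genes of a library are not independent, so the excess is not a test. Without 1a replicate 1, 1a replicate 3, untreated replicate 2 or untreated replicate 3, the higher genes numbered 1410, 1526, 1527 and 1570, and the 2-fold count was 270 without 1a replicate 2. With upper-quartile scaling the balance turned round, with 3114 higher and 2371 lower. Against a 1.2-fold change, 189 were higher and 217 lower, and with the share of reads outside features as a covariate 574 were higher and 714 lower. The 2-fold count was 300 without a count filter, 98 over protein-coding genes only, 76 with DESeq2, 61 against a 1.2-fold change, and 68 both with CPM over 1 in at least 3 libraries and with that covariate.

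Fold changes followed transcript length and GC content. Across 11350 genes, which are not independent replicates, Spearman's rho with the log2 fold change was -0.51 for length and 0.45 for GC. The quintile of shortest transcripts had a median log2 fold change of 0.14 and the quintile of longest -0.18. After removal of the trend, 2078 genes were higher and 2155 lower, and 2930 of the 5303 calls kept their direction and their call. Another 1289 genes were called only after removal. The median of the ribosomal protein list went from 0.19 to 0.10, with 16 of 30 members called higher where 27 had been. The medians of the unfolded protein response, aminoacyl-tRNA synthetase and stem and progenitor lists went from -0.35 to -0.28, from -0.07 to -0.05 and from -0.15 to -0.06. Those of the MAPK, lysosome and autophagy, and glycolysis lists went from 0.11 to 0.03, from 0.19 to 0.13 and from 0.14 to 0.11. Those of the aryl hydrocarbon receptor, NRF2, proteasome, and NF-kB lists went from 0.18 to 0.39, from 0.72 to 0.77, from 0.20 to 0.21 and from 0.41 to 0.40. Called members after removal numbered 18 higher and 0 lower for the NRF2 list, 16 and 1 for lysosome and autophagy, 7 and 0 for NF-kB, 4 and 1 for MAPK, 17 and 0 for the proteasome, 8 and 2 for glycolysis, 3 and 0 for the aryl hydrocarbon receptor, 1 and 15 for the unfolded protein response, 2 and 6 for aminoacyl-tRNA synthetases, and 1 and 5 for the stem and progenitor list. Of the 11 called lists, 9 were still called. The MAPK list (adjusted p = 0.145) and the stem and progenitor list (0.132) were not. A further 3 lists were called lower only after removal, namely granulocyte markers (0 members higher and 4 lower, median -0.11, camera adjusted p = 1.95e-05), DNA replication genes (0 higher and 10 lower, median -0.06, adjusted p = 0.000375) and mitochondrially encoded genes (1 higher and 6 lower, median -0.07, adjusted p = 0.0180). With an estimated correlation after removal, these 3 had an adjusted p = 0.457, 0.507 and 0.604, and the lowest over all lists was 0.0904. Among named genes, NPIPA8, CDK6, TIPARP, RPL10A, ETV4, SLC7A11 and HOXA9 were no longer called, and AHR (log2 fold change 0.39, edgeR adjusted p = 0.00848) and GCLC (0.18, edgeR adjusted p = 0.0108) were called.

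**Figure D3:**
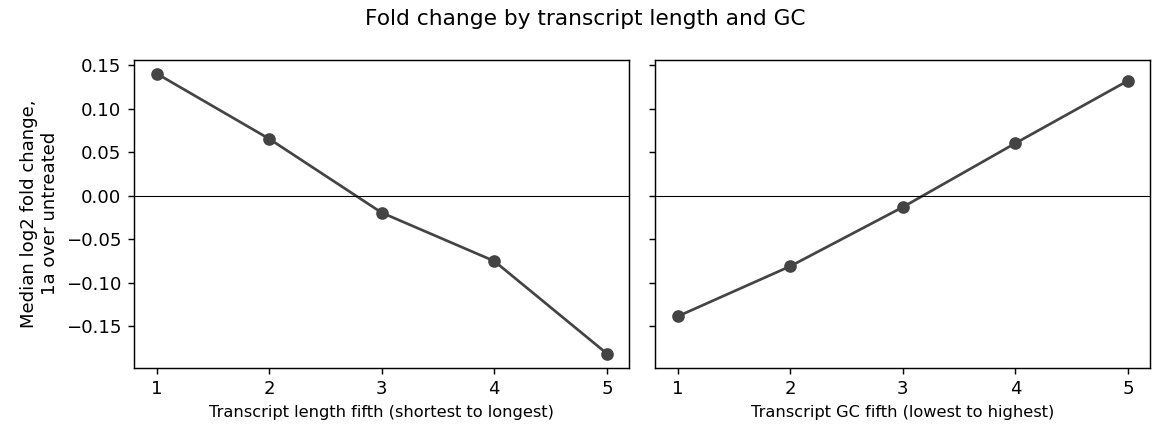
Median log2 fold change of 1a over untreated in quintiles of genes by transcript length (left) and by transcript GC content (right). The medians went from 0.14 in the shortest to -0.18 in the longest quintile, and from -0.14 at the lowest to 0.13 at the highest GC.

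Of the 40 genes in the authors' deposited lists, 36 were called in the same direction, 18 from each list. The lists were chosen on these libraries and are not independent evidence. LUCAT1, EGF and the listed identifier for AC107983.2 were below the count filter, and NCR3LG1 was not called (log2 fold change -1.04, edgeR adjusted p = 0.0536). These were named after their values were seen. The authors' deposited table gave NQO1 a log2 fold change of 1.80, HMOX1 2.14 and BMP8A -2.51.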

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

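The tests of the trend as the whole source of the calls, of the trend on 7 of the 11 called lists, of the ferritin copies and of the not-unique reads were chosen after their results had been seen, as was the bootstrap interval on the lists.

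A summary outside the gene counts differed between the groups. Reads aligned to more than 1 place made up 8.0% ± 0.08 of all reads tabulated with 1a and 7.6% ± 0.21 without (SD, n = 3), a difference of 0.440 percentage points with every 1a library above every untreated one. The exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give. Ferritin is a candidate source, because FTL and FTH1 have near-identical copies. The 5 tested ferritin pseudogenes had a median log2 fold change of 1.17, of which 4 were called higher, against 0.03 for 1031 other processed pseudogenes. That median is near the FTL and FTH1 values of 1.23 and 1.65, so reads shared with those genes may account for the pseudogenes. Whether ferritin reads also make up the 0.440 points stays open, since the tables do not name the genes behind reads aligned to more than 1 place.

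The many small calls are a second pattern. The real grouping gave 5303 calls and the highest of the other 9 splits gave 1, but 1 of 10 splits is the smallest share this design allows, so chance cannot be judged from it. A trend on the length and GC of the longest annotated transcript is argued against as the whole source. After its removal 55.3% of the calls kept their direction and their call. The slope of log2 expression on log2 length varied among libraries of a group, with a range of at least 0.645 of the difference between group means. Among the 1a libraries, replicate 2 stood apart (0.0016 against -0.069 and -0.067). Library-to-library variation in length recovery may therefore account for part of the small calls, and an effect of 1a on long transcripts stays open and untested. The slopes per 10% of GC were 0.029 to 0.054 with 1a and -0.070 to -0.026 without, and their spread was not tested.

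The third pattern is the 11 called gene lists, tested against this trend. The bootstrap drew each list's members again 1000 times, with the libraries and the removal held fixed. Its intervals therefore hold no spread between libraries, and they treat the members of a list as independent. After its removal the NRF2 list had 107% of its median, with a bootstrap 95% interval from 78.2% to 120%, the proteasome list 102% (70.0% to 145%), and the unfolded protein response list 79.7% (65.0% to 123%). The NF-kB list had 98.6% (56.4% to 131%) and the lysosome and autophagy list 66.6% (51.5% to 172%). All these lists were still called, which argues against the trend, as measured on each gene's longest annotated transcript, as their whole source. Expressed transcripts can be shorter, and a trend on their lengths was not tested. The aryl hydrocarbon receptor list was still called and had 216% (57.0% to 216%). With 5 members its median is the value of AHR alone, so that share cannot judge the trend for the list. The ribosomal protein list had 54.6% of its median (37.5% to 76.1%, adjusted p = 1.69e-05), which is above the bound of 50% set before the test. Over the resampled members, part of its median went with the trend and part remained after removal, with the spread between libraries not covered. Which part is larger stays open, because the interval, a requirement added after that value was seen, spans 50%. The glycolysis list, with 77.8% (43.8% to 331%), was still called, and the trend's share of its median stays open for the same reason. The aminoacyl-tRNA synthetase list, with 68.4% (-52.5% to 414%), was still called (camera adjusted p = 0.0180). The trend's share of its median cannot be judged, because its interval spans 50%. The stem and progenitor list had 39.0% (-135% to 359%, adjusted p = 0.132) and the MAPK list 30.7% (-128% to 182%, adjusted p = 0.145). Both lost their calls as the trend would have it, and they cannot be told apart from it, because their intervals span 50% as well. For the lists where the trend was argued against, an effect of 1a is the hypothesis that the design names. The estimated-correlation values in the report are 1 limit. No vehicle is named for the untreated cells and separate cultures are not stated. Differences of vehicle, handling or culture therefore cannot be told apart from an effect of 1a.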

How the results depend on the processing

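None of the 75 genes and 11 lists followed changed direction in any alternative run on them, but upper-quartile scaling turned the balance of calls from more lower to more higher (3114 higher and 2371 lower). Without a count filter, 300 genes changed at least 2-fold and 18 lists were called. The 2-fold count was 68 with CPM over 1 in at least 3 libraries, 76 with DESeq2 and 98 over protein-coding genes only. Lists called numbered 7 with limma-voom. They numbered 0 with an estimated correlation, both before and after removal of the trend on transcript length and GC content. Fry, which asks whether a list changed and not whether it differs from the other genes, called 19. At an adjusted p under 0.01, 1236 genes were higher and 1711 lower. With 1 library left out, 1410 to 2957 genes were higher, 1888 to 3223 lower and 126 to 270 changed at least 2-fold. Of the alternatives chosen after seeing the data, the test against a 1.2-fold change gave 189 higher, 217 lower and 61 at least 2-fold, and the share of reads outside features as a covariate gave 574, 714 and 68. Except where fewer genes, fewer libraries or a stricter threshold were used, the cause was not tested. The labels do not say that a shared replicate number marks a shared day or batch, so it was not a block in the main fit. Deviations of same-numbered libraries had correlations of 0.0975, -0.0358 and -0.0044. With the replicate block 2756 genes were higher and 3051 lower, against 2481 and 2822 in the main fit. No call of a named gene or of a called list was lost with that block. With 1 library left out, 13 calls of named genes and 6 of lists were lost and 437 and 60 were the same. Upper-quartile scaling moved the share of calls that were higher from 46.8% to 56.8%.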

Other observations

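Genes outside the fixed lists were grouped by function after the main results were seen, and what each test would show was written down before these groups were tested. Glutathione, peroxiredoxin and detoxification enzymes rose in 16 of 24 tested members and fell in 1, with a median log2 fold change of 0.21 (camera adjusted p = 1.17e-08). With an estimated correlation the adjusted p = 0.236, and after removal of the length and GC trend the median was 0.12 (adjusted p = 5.02e-07). EPHX1, an epoxide hydrolase, rose from 73.7 to 121 CPM, and PRDX1, MGST1 and CBR1 had log2 fold changes of 0.55, 0.55 and 0.51. UGDH was the member that fell (-0.30). These values are consistent with the hypothesis that the rise of the NRF2 list, at a median of 0.21 here, extends to further enzymes of the same kind.

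For heme and iron handling genes outside the NRF2 list, the same hypothesis was negative as a group shift in 1 direction. HMOX1, FTL and FTH1 are in the NRF2 list and were therefore not in this group. Of 18 tested members, 7 rose and 4 fell, with a median log2 fold change of -0.0277 (camera adjusted p = 0.425). After removal of the length and GC trend the median was 0.00872 (camera adjusted p = 0.389). Camera looks for a shift in 1 direction, so members that move both ways can go uncalled. BLVRB, biliverdin reductase B, rose by 0.83 on the log2 scale, while TFRC, the transferrin receptor, and IREB2, which binds iron-responsive elements, fell by 0.21 and 0.33. The regulators of NRF2 were not called as a group either, with a median of 0.0733 (adjusted p = 0.361) and 3 of 8 members higher. KEAP1 and MAFG rose by 0.27 and 0.35, NFE2L2, which encodes NRF2, rose by 0.13, and BACH1, a repressor of HMOX1, fell by 0.38 on the log2 scale. All genes in these paragraphs were named after their values were seen. The fold changes of single members are those before removal of the trend.

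The authors' deposited table pairs AC107983.2 with the identifier ENSG00000227077 and a log2 fold change of -1.26. The count tables give that identifier the symbol AC107983.1 and 1, 1 and 1 counts with 1a against 0, 1 and 0 without.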
